A study of Homo sapiens with 15 samples.

How the data were processed

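The samples were Caco-2 cells, a human colorectal carcinoma line that forms an enterocyte-like monolayer when confluent. Per the labels, monolayers were exposed for 24 h to a dishwasher rinse aid diluted 1:10000 or 1:40000, or were left unexposed as controls, with 5 libraries in each of 3 groups. Per the labels' protocols, RNA was isolated with the RNeasy Plus Micro Kit and polyadenylated RNA was made into libraries with the TruSeq RNA Kit. Nothing in the labels says whether replicates came from separate cultures, so p values measure only the spread between these samples.

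The deposited files held raw counts per Ensembl gene, 1 file per library. The submitters' processing notes name cutadapt, STAR 2.7.9a, featureCounts, DESeq2 1.32.0 and GRCh38, without giving the role or order of each. Per the file headers, the 5 control files came from RNA STAR and all 10 rinse aid files came from HISAT2. The control files listed 60649 genes and the rinse aid files 61544, so the annotation differed as well, and neither the annotation release nor the strand setting was stated. Aligner and annotation therefore cannot be told apart from exposure in the comparisons with control, while the comparison between the dilutions shares both.

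Genes were joined by Ensembl identifier without version. The files shared 60557 identifiers, 3798 of them with a changed version, with 48 only in the control files and 941 only in the rinse aid files. At least 99.977% of each library's counts lay in shared genes. Symbols were found for 60553 shared identifiers. GENCODE 29 on GRCh38, the annotation at hand, held 58298 and gave coordinates, biotypes and overlaps. Without a stated strand setting, counts of overlapping and antisense genes are uncertain, as are counts of genes with near-identical copies.

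Total counts ran from 4333226 to 14230853 in the controls, from 5489425 to 9555632 at 1:10000 and from 2551839 to 172092447 at 1:40000. Folds against a group with 0 counts were given as bounds against 3 counts over the group, and ratios with 1 to 3 counts carry an exact counting interval. These bounds and intervals cover counting error only.

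The fit was made in R 4.3.3 with edgeR 4.0.16, using trimmed mean of M-values (TMM) scaling, filterByExpr by group, 3 group means and the robust quasi-likelihood test. It tested 13157 genes. Benjamini-Hochberg adjustment was made within each of 3 comparisons, namely 1:10000 with control, 1:40000 with control and 1:10000 with 1:40000. A gene was called at an adjusted p under 0.05. Means are TMM-normalised counts scaled to a common library size, in CPM, ± SD over 5 libraries, and log2 fold changes are ± SE. This SE is approximate, the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Principal components used log CPM with a prior count of 2.

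Lists of genes, 39 in all with 703 members, each member found in the files, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01. The 36 lists with at least 5 tested members entered, and adjustment was over lists within a comparison. The lists cover junctions (tight junctions, adherens junctions and desmosomes), enterocyte function (brush border, ion and water transport, lipoprotein assembly, mucins, antimicrobial products), and lipids (cholesterol synthesis, fatty acid synthesis, fatty acid oxidation). They also cover stress (integrated stress response, unfolded protein response, NRF2 targets, heat shock, xenobiotic metabolism, metallothioneins), inflammation (cytokines, NF-kB targets, interferon response) and growth (immediate early genes, EGFR ligands and repair, YAP targets, apoptosis, mitosis, DNA replication, stem cell and Wnt targets). The rest were metabolism (glycolysis, hypoxia, nuclear-encoded respiratory chain, mitochondrially encoded transcripts, lysosome), ribosomal proteins, histones, epithelial-mesenchymal transition, and markers of squamous, fibroblast, leukocyte, enteroendocrine and hepatocyte cells.

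The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. For each comparison with control the rule takes the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 5 CPM over the compared libraries, non-overlapping groups and a symbol that is not clone-based. Between the dilutions it takes 4 and 4. It adds, in the comparisons with control, the 2 called members with the smallest adjusted p in the direction of each called list, and always 3 called members of the tight junction and cytokine lists. Other genes named were chosen after their values were seen, as the text states. Some genes that the rule would name are not reported here.

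Genes were near absent in 1 set of files when both rinse aid groups lay at least 32-fold from control and the higher side reached 2 CPM. A clean subset of 4519 protein-coding genes left out those with a pseudogene, an exon overlap, a changed version, a near absent call or a transcript outside the primary assembly in the GENCODE 29 metadata. Near absence, this subset and 5 further alternatives (libraries thinned to the smallest total, 1:40000 without its deepest and shallowest library, library sizes without mitochondrially encoded genes, genes with copies outside the primary assembly left out, and calls limited to genes with the same direction between the dilutions) were chosen after seeing the data. The alternatives fixed beforehand were other scalings, other low-count filters, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, a replicate block, a 2-fold threshold, each library left out, estimated inter-gene correlation, fry and split controls.

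The agreement between the dilutions was compared with 10 simulated sets of unchanged groups against the same controls and with 20 assignments of split controls. Tested on simulated data at the real means and depths, the fit recovered, for 1:10000 with control, 64.2% of genes changed 1.5-fold, 85.1% at 2-fold and 100% at 4-fold, with 5.7% of calls false. The shares were 65.7%, 88.1% and 100% with 5.6% false for 1:40000 with control, and 68.7%, 88.1% and 98.5% with 5% false between the dilutions. In each, the simulated changed list was called, and of 30 unchanged lists 1 was called in the first comparison and 0 in the others. Simulated genes were drawn independently, and only 67, 67 and 66 of 13157 were changed at 1.5-fold, 2-fold and 4-fold. These shares therefore do not cover correlated genes, or changes in as many genes as were called in the real data. Tables and plots used pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.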

Results

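Polyadenylated RNA of Caco-2 monolayers was sequenced in 15 libraries, 5 from unexposed cells, 5 from cells exposed to rinse aid at 1:10000 and 5 from cells exposed at 1:40000. Rinse aid is the surfactant-based liquid that a dishwasher releases in its final rinse, and the stronger solution was 4 times as concentrated as the weaker. Library totals differed most at 1:40000, where replicate 1 held 172092447 counts and replicate 2 held 2551839, a ratio of 67.4. The first principal component carried 72.9% of the variance and separated the controls from all rinse aid libraries, and the second carried 11.5% and separated the dilutions. The first of these follows the aligner named in the file headers as well as the exposure.

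Libraries also differed in the kinds of RNA they held. Mitochondrial ribosomal RNA made up 0.216 to 0.349% of counts in the controls, 3.11 to 3.83% at 1:10000 and 0.626 to 1.24% at 1:40000. Mitochondrial messenger RNA made up 1.14 to 1.45%, 2.57 to 3.32% and 1.24 to 2.06% of counts in the same order. At 1:40000, replicates 1 and 2 held 2.06 and 1.91% mitochondrial messenger RNA, above the other 3. Pseudogenes held 0.213 to 0.248% of counts in the controls, 0.686 to 0.728% at 1:10000 and 0.625 to 0.669% at 1:40000.

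**Figure D1:**
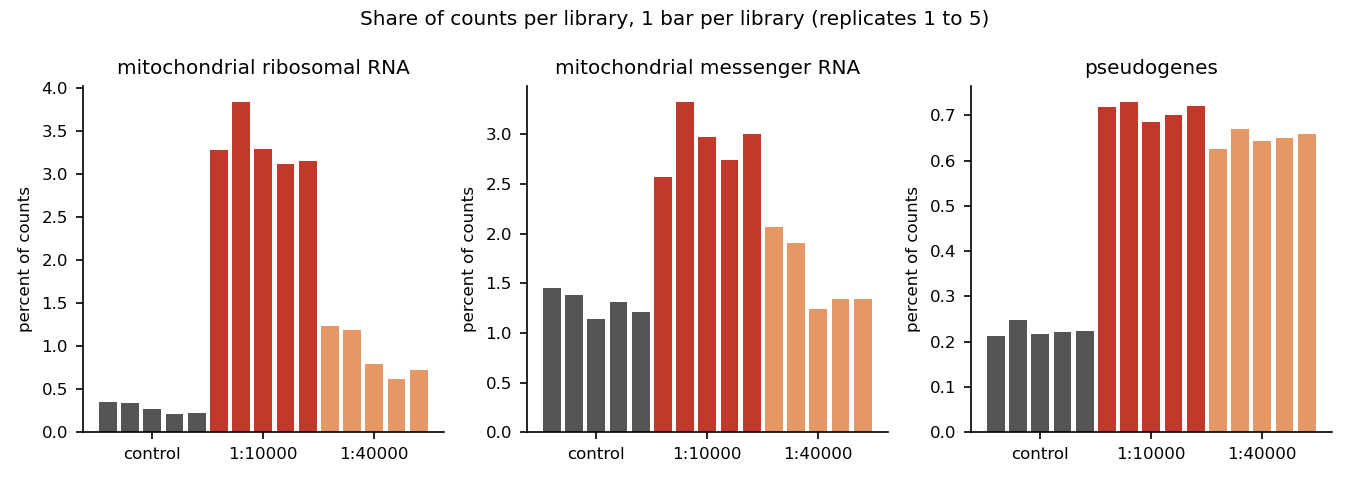
Percent of all counts (vertical axes) that each of the 15 libraries gave to mitochondrial ribosomal RNA, mitochondrial messenger RNA and pseudogenes, 1 bar per library by group. All rinse aid libraries lay above the control range of 0.216 to 0.349% for mitochondrial ribosomal RNA and above 0.248% for pseudogenes.

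At 1:10000, stress, early response, repair and cytokine genes were higher than in unexposed cells, and genes of lipid export, enterocyte identity and cell division were lower. Of the lists behind this only the integrated stress response passed with an estimated correlation too. ATF3, a transcription factor induced by cellular stress, rose from 6.37 ± 1.07 to 105 ± 14.9 normalised counts in CPM (mean ± SD, n = 5), a log2 fold change of 4.04 ± 0.12 (± SE). ANKRD1, a target of the YAP growth pathway, rose from 35 ± 8.01 to 672 ± 63.8. APOB, the structural protein of intestinal lipoproteins, fell from 945 ± 129 to 154 ± 17.7, and MKI67, a marker of dividing cells, fell from 351 ± 12.5 to 74.1 ± 6.34. In GENCODE 29 on GRCh38, the protein-coding genes ATF3 (ENSG00000162772), ANKRD1 (ENSG00000148677), APOB (ENSG00000084674) and MKI67 (ENSG00000148773) lie on chromosome 1 from 212565334 to 212620777, chromosome 10 from 90912096 to 90921276, chromosome 2 from 21001429 to 21044073 and chromosome 10 from 128096659 to 128126385. The comparison asks what the stronger dilution does to the epithelial monolayer in 24 h. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9343 of 13157 genes passed, 4584 higher and 4759 lower, of which 1541 and 1529 changed at least 2-fold. Every library of one group lay above every library of the other for 7599 genes (57.8%), which chance gives for 0.79%. Aligner and annotation cannot be told apart from exposure here. In the clean subset of protein-coding genes without an annotated pseudogene, an exon overlap or a changed model, chosen after seeing the data, 3234 of 4519 genes (71.6%) passed. The lists of brush border, mitosis and DNA replication were not called in that subset, and lipoprotein assembly could not be tested there.

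Among the lists that rose at 1:10000 against control, the integrated stress response, genes of the ATF4 program, had 19 of 20 tested members higher and 0 lower, with a median log2 fold change of 2.07 (camera with Benjamini-Hochberg adjustment, adjusted p = 5.15e-20; adjusted p = 0.00633 with an estimated correlation). TRIB3, a pseudokinase of that program, rose from 77.7 ± 5.97 to 562 ± 33.0. Immediate early genes had 19 of 22 higher and 1 lower (median 1.57, camera adjusted p = 1.73e-08; adjusted p = 0.249 with an estimated correlation). Among them were ATF3 and the transcription factor KLF6, which rose from 48.6 ± 2.51 to 195 ± 18.1. YAP targets had 12 of 14 higher and 0 lower (median 0.96, camera adjusted p = 7.81e-06; adjusted p = 0.0896 with an estimated correlation). ANKRD1 rose by 4.25 ± 0.14 and CRIM1, a membrane protein that binds bone morphogenetic proteins, by 1.23 ± 0.07. The list of EGFR ligands and epithelial repair had 15 of 17 higher and 1 lower (median 1.39, camera adjusted p = 9.72e-05; adjusted p = 0.339 with an estimated correlation). In it EGFR, the epidermal growth factor receptor, rose from 75.6 ± 6.70 to 157 ± 11.8, and TGM2, a protein-crosslinking transglutaminase, rose from 119 ± 9.66 to 246 ± 28.7. The CRIM1 locus also has transcripts outside the primary assembly. Of the 19 lists called at 1:10000 against control, 8 higher and 11 lower, 7 were also called in the clean subset, where lists hold fewer members.

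NF-kB targets were higher for 10 of 13 and lower for 2 (median 1.04, camera adjusted p = 0.00377; adjusted p = 0.308 with an estimated correlation). ICAM1, an adhesion molecule for leukocytes, rose from 27.6 ± 2.62 to 112 ± 5.63, and NFKB2, a precursor of an NF-kB subunit, rose from 23.4 ± 2.15 to 122 ± 9.73. Of the 32 cytokines and chemokines fixed, 10 were tested and 9 were higher with 0 lower (median 1.15, camera adjusted p = 0.00776; adjusted p = 0.2 with an estimated correlation). CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose from 1.10 ± 0.591 to 14.7 ± 3.00, IL32, an inflammatory cytokine, from 63.3 ± 9.34 to 151 ± 15.4, and IL18, a cytokine processed by inflammasomes, from 33.7 ± 5.56 to 84.3 ± 10.9. NRF2 targets had 12 of 18 higher and 4 lower (median 0.48, camera adjusted p = 0.0288; adjusted p = 0.434 with an estimated correlation). SLC7A11, the cystine importer, rose by 2.21 ± 0.10 and ME1, an NADPH-producing enzyme, by 1.03 ± 0.07. SLC7A11 is also a member of the integrated stress response list and ME1 of the fatty acid synthesis list. ATF3 is in both the stress response and the immediate early list, so list calls are not independent of each other. Mitochondrially encoded transcripts had 9 of 13 higher and 2 lower (median 1.09, camera adjusted p = 0.028; adjusted p = 0.459 with an estimated correlation). Adjusted over the list alone, 11 were higher and 2 lower. The cytochrome oxidase subunits MT-CO1 and MT-CO3 rose by 1.78 ± 0.17 and 1.54 ± 0.12. For the other lists called at 1:10000 against control, the counts adjusted over the list alone were the same as those over all genes.

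**Figure D2:**
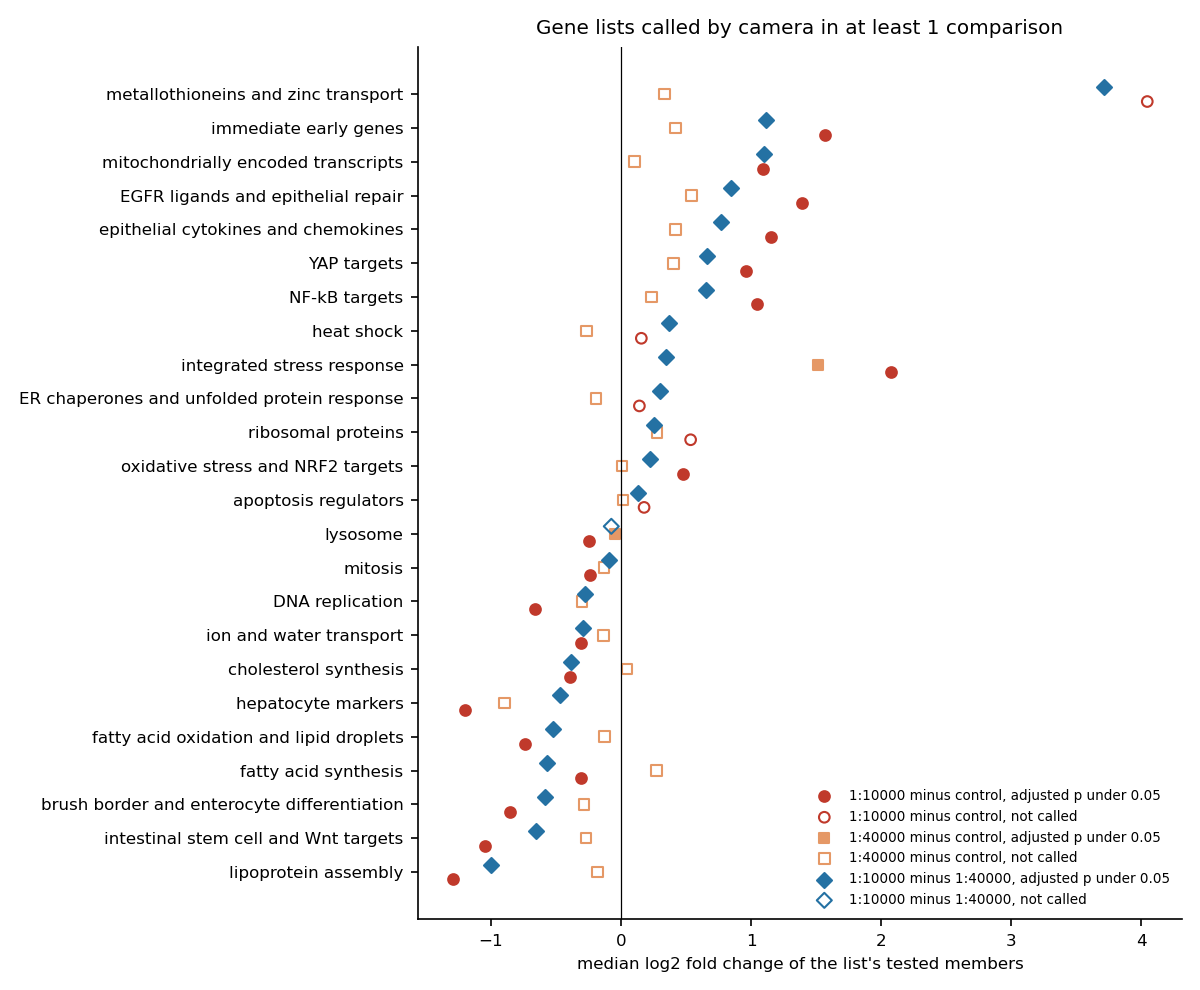
Median log2 fold change (horizontal axis) of the tested members of each list called in at least 1 comparison (vertical axis), with red circles for 1:10000 against control, orange squares for 1:40000 against control and blue diamonds for 1:10000 against 1:40000, filled where the camera adjusted p passed. The integrated stress response stood at 2.07, 1.52 and 0.35 and was filled in all 3 comparisons.

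Lists that fell at 1:10000 against control concerned lipid handling, the enterocyte program and proliferation, but in the clean subset only 1 of these 11, ion and water transport, was still called, against 6 of the 8 higher ones, where NRF2 targets and mitochondrially encoded transcripts lost theirs (camera adjusted p = 0.634 and 0.179). There the calls ended for brush border (camera adjusted p = 0.118), fatty acid oxidation (0.145), DNA replication (0.0731), mitosis (0.179), stem cell and Wnt targets (0.356), cholesterol synthesis (0.179) and hepatocyte markers (0.177), and lipoprotein assembly had too few members to be tested. Lipoprotein assembly had 0 of 12 members higher and 8 lower (median -1.29, camera with Benjamini-Hochberg adjustment, adjusted p = 0.00468; adjusted p = 0.422 with an estimated correlation). APOB changed by -2.62 ± 0.13 and DGAT2, which catalyses the last step of triglyceride synthesis, by -1.33 ± 0.08. The brush border list had 3 of 19 higher and 13 lower (median -0.86, camera adjusted p = 0.00504; adjusted p = 0.422 with an estimated correlation). HNF4A and CDX2, transcription factors of intestinal identity, fell from 572 ± 42.8 to 217 ± 16.4 and from 172 ± 15.5 to 63.0 ± 7.21. Fatty acid oxidation had 2 of 14 higher and 10 lower (median -0.74, camera adjusted p = 0.0081; adjusted p = 0.422 with an estimated correlation). The peroxisomal enzyme EHHADH stood at -1.84 ± 0.07 and the fatty acid binding protein FABP1 at -2.26 ± 0.13. Cholesterol synthesis had 4 of 23 higher and 14 lower (median -0.39, camera adjusted p = 0.0327; adjusted p = 0.459 with an estimated correlation). LSS, an enzyme of its late steps, stood at -3.30 ± 0.12. Fatty acid synthesis had 2 of 13 higher and 11 lower (median -0.31, camera adjusted p = 0.0325; adjusted p = 0.422 with an estimated correlation). FASN, the fatty acid synthase, stood at -0.69 ± 0.06, and ACACA, which supplies its substrate, was near absent in the rinse aid files. LSS and ACACA have transcripts outside the primary assembly. With such genes left out the calls of both synthesis lists ended (camera adjusted p = 0.0692 and 0.132), and in the clean subset fatty acid synthesis turned direction (camera adjusted p = 0.947).

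DNA replication genes had 2 of 22 higher and 16 lower at 1:10000 (median -0.67, camera with Benjamini-Hochberg adjustment, adjusted p = 0.00153; adjusted p = 0.422 with an estimated correlation). FEN1, the nuclease that trims Okazaki fragments, changed by -1.67 ± 0.11, and MCM3, a subunit of the replicative helicase, by -0.96 ± 0.08. Mitosis genes had 3 of 19 higher and 10 lower (median -0.24, camera adjusted p = 0.00989; adjusted p = 0.459 with an estimated correlation). MKI67 stood at -2.24 ± 0.07 and the kinetochore protein CENPF at -1.69 ± 0.06. Stem cell and Wnt targets had 1 of 14 higher and 11 lower (median -1.05, camera adjusted p = 0.00745; adjusted p = 0.2 with an estimated correlation). The crypt receptor EPHB2 stood at -1.51 ± 0.09 and ZNRF3, a ligase that removes Wnt receptors, at -1.23 ± 0.10. Ion and water transport had 1 of 14 higher and 6 lower (median -0.31, camera adjusted p = 0.0472; adjusted p = 0.339 with an estimated correlation). AQP3, a water and glycerol channel, fell from 135 ± 17.4 to 18.9 ± 1.51 and the sodium pump subunit ATP1B1 changed by -1.13 ± 0.08. This last call ended without control replicate 1, 1:10000 replicate 3 or 1:10000 replicate 4 (camera adjusted p = 0.0534, 0.0581 and 0.0568). Of 12 hepatocyte markers, 10 were expressed enough in these Caco-2 libraries to be tested. Of these 0 were higher and 9 lower (median -1.20, camera adjusted p = 0.0181; adjusted p = 0.472 with an estimated correlation), and fibrinogen FGA stood at -3.75 ± 0.21 and the retinol carrier RBP4 at -0.57 ± 0.07. The lysosome list had 6 of 20 higher and 11 lower (median -0.25, also with NEU1 at its bound, camera adjusted p = 0.0405; adjusted p = 0.422 with an estimated correlation). Its member NEU1, a sialidase, was near absent in the rinse aid files, and without such genes the call ended (camera adjusted p = 0.794). It also ended with the replicate block and with 1:40000 used without its deepest and shallowest library (camera adjusted p = 0.0556 and 0.057).

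**Figure D3:**
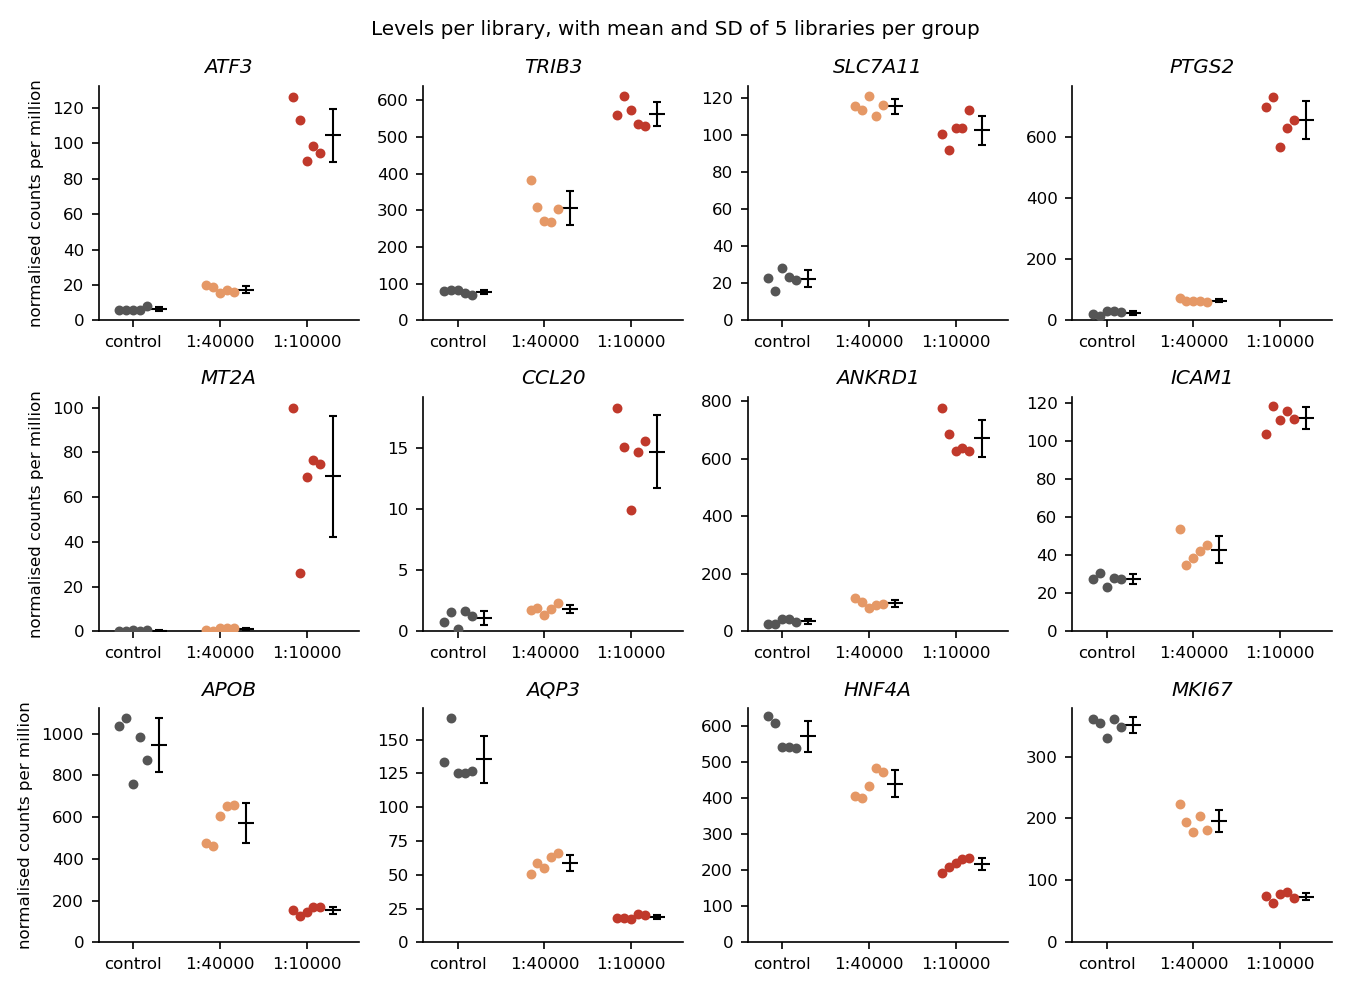
Normalised CPM (vertical axes) of ATF3, TRIB3, SLC7A11, PTGS2, MT2A, CCL20, ANKRD1, ICAM1, APOB, AQP3, HNF4A and MKI67 in each library (points) with the mean and SD of each group (n = 5). PTGS2 stood at 25.4 ± 6.77 in the controls, 655 ± 63.2 at 1:10000 and 63.8 ± 4.85 at 1:40000, and APOB at 945 ± 129, 154 ± 17.7 and 571 ± 95.5.

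The series concerns the gut epithelial barrier, and tight junction genes moved in both directions at 1:10000. PARD3, a polarity scaffold, rose from 88.7 ± 4.80 to 182 ± 13 and PATJ, another scaffold of junction and polarity complexes, from 26.6 ± 2.56 to 57.5 ± 5.03. TJP1, the zonula occludens scaffold, stood at 86.8 ± 4.05 in the controls and 2.18 ± 0.966 at 1:10000, but it is among the genes near absent in both rinse aid groups. Of 22 tight junction genes, 7 were higher and 9 lower, the same as adjusted over the list alone (median -0.26, camera adjusted p = 0.537), so the list as a whole did not pass. Adherens junctions and desmosomes had 4 of 15 higher and 7 lower, or 5 and 7 adjusted over the list alone (camera adjusted p = 0.551), and mucins and goblet cell products 1 of 8 higher and 3 lower (camera adjusted p = 0.658).

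Other lists did not pass at 1:10000 against control, and their counts adjusted over the list alone were the same except where given. Metallothioneins and zinc transport had 4 of 6 higher and 1 lower (median 4.05, camera adjusted p = 0.0582, or 0.0347 with the replicate block), and ribosomal proteins 25 of 30 higher and 2 lower (camera adjusted p = 0.119), with a median of 0.54 but a mean of -0.30. RPS18 and RPS9 in that list were near absent in the rinse aid files. Epithelial-mesenchymal transition had 5 of 6 higher and 0 lower, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.185). The higher and lower counts were 6 and 5 of 11 for xenobiotic metabolism (camera adjusted p = 0.291), 11 and 7 of 23 for apoptosis regulators (camera adjusted p = 0.291; 11 and 8 adjusted over the list alone) and 9 and 7 of 18 for the unfolded protein response (camera adjusted p = 0.351). They were 9 and 8 of 19 for glycolysis (camera adjusted p = 0.748), 4 and 4 of 13 for hypoxia (camera adjusted p = 0.791), 3 and 10 of 25 for the nuclear-encoded respiratory chain (camera adjusted p = 0.553) and 6 and 4 of 12 for heat shock (camera adjusted p = 0.769). The interferon response had 5 and 5 of 13 (camera adjusted p = 0.76), antimicrobial products 3 and 3 of 7 (camera adjusted p = 0.984), histones 2 and 3 of 11 (camera adjusted p = 0.703) and fibroblast markers 0 and 3 of 5 (camera adjusted p = 0.22). For heat shock (0.16 and -0.002), hypoxia (0.21 and -0.02), the interferon response (-0.02 and -0.14, tested as higher) and antimicrobial products (0.34 and 0.001, tested as lower), the median, the mean and the direction of the test differed in sign. Too few squamous (2 of 12), leukocyte (4 of 12) and enteroendocrine or tuft cell markers (1 of 14) passed the count filter for a list test, with 1, 2 and 0 lower and 0, 1 and 0 higher.

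At 1:40000, the integrated stress response rose again. SLC7A11, the cystine importer of that program, rose from 22.6 ± 4.45 to 116 ± 4.00 CPM (log2 fold change 2.38 ± 0.10), and STC2, a secreted glycoprotein induced by stress, rose from 103 ± 7.27 to 295 ± 9.33 (1.52 ± 0.06). SLC7A11 (ENSG00000151012) lies on chromosome 4 from 138164097 to 138242349 and STC2 (ENSG00000113739) on chromosome 5 from 173314713 to 173329503. The list had 19 of 20 members higher and 0 lower, or 20 and 0 adjusted over the list alone (median 1.52, camera with Benjamini-Hochberg adjustment, adjusted p = 2.72e-20; adjusted p = 0.00967 with an estimated correlation). The comparison asks which changes remain when the rinse aid is diluted a further 4 times. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6858 of 13157 genes passed, 3439 higher and 3419 lower, of which 878 and 483 changed at least 2-fold. The even split depended on the scaling, with 4031 higher and 2900 lower under upper-quartile scaling. Groups did not overlap for 4771 genes (36.3%, against 0.79% by chance). Aligner and annotation cannot be told apart from exposure here. In the clean subset 2333 of 4519 genes (51.6%) passed.

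Tight junction genes were again mixed at 1:40000. OCLN, the membrane protein occludin, fell from 39.0 ± 2.93 to 9.35 ± 1.30, PARD3 rose from 88.7 ± 4.80 to 142 ± 14.8, and TJP1 was near absent at 2.08 ± 1.19. Both OCLN and TJP1 have transcripts outside the primary assembly. The list had 5 of 22 higher and 6 lower, with the same counts adjusted over the list alone (median -0.09, camera adjusted p = 0.176). Of 10 tested cytokines and chemokines 3 were higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 0.591), namely IL32 at 0.52 ± 0.10, IL18 at 0.47 ± 0.12 and CXCL16, a chemokine that also exists in a membrane-bound form, at 0.29 ± 0.06. Lysosome genes were called lower (4 higher and 7 lower of 20, with the same counts adjusted over the list alone, median -0.05, mean -1.15, camera adjusted p = 0.00297; adjusted p = 0.259 with an estimated correlation). The median turned positive under upper-quartile scaling, NEU1 was near absent, and without such genes the call ended (camera adjusted p = 0.493). Proliferation and early response genes moved in part, with 1 of 22 DNA replication genes higher and 17 lower (camera adjusted p = 0.159), 11 of 22 immediate early genes higher and 1 lower, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.169), and 10 of 14 YAP targets higher and 0 lower, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.176). These and the remaining lists tested did not pass in the main fit. With the replicate number as a block, lists called at 1:40000 became 5, adding EGFR ligands and repair, DNA replication and hepatocyte markers (camera adjusted p = 0.0484, 0.0384 and 0.0234). Still more lists were called when the near absent genes were left out, with lysosome lost, as given with the processing below. Lists that did not pass in the main fit are therefore not shown to be unchanged at 1:40000. Fatty acid synthesis had a median of 0.27 and a mean of -0.23, and ribosomal proteins 0.28 and -0.50, so median and mean differed in sign. Median, mean and direction of the test also differed in sign for adherens junctions, ion and water transport, apoptosis regulators and glycolysis at 1:40000.

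The largest fitted changes against control were in genes with almost no counts in 1 set of files. The lowest at 1:10000 were PRPF8, a core protein of the spliceosome, RPS18, a ribosomal protein, PSMB3, a proteasome subunit, TAF15, an RNA-binding protein, NEU1 and DDR1, a collagen receptor. In the controls they held 448 ± 22.9, 1008 ± 59.5, 147 ± 12.5, 109.7 ± 2.31, 105 ± 9.25 and 103 ± 5.77 CPM. At 1:10000 all 5 libraries had 0 counts of PRPF8, PSMB3, TAF15, NEU1 and DDR1, at least 5140-fold, 1690-fold, 1260-fold, 1200-fold and 1170-fold lower, and RPS18 had 1 count against 42958 in the controls, a ratio of 34700 with a counting interval of 6220 to 1370000. At 1:40000 the lowest were PSMB3, DDR1, MRPS5, a mitochondrial ribosomal protein, and SLC39A7, a zinc transporter, with 0 counts and at least 10900-fold, 7620-fold, 5370-fold and 4950-fold lower, together with RPS18 and PRPF8. These bounds rest largely on the deepest library, and without it they were 2420-fold, 1680-fold, 1190-fold and 1090-fold. PRPF8 had 3 counts against 19254, a ratio of 33300 with a counting interval of 11400 to 162000, but without the deepest library it had 0 counts and a bound of 7370-fold, and RPS18 stood at 0.0320 ± 0.0466 CPM. PRPF8 lies on chromosome 17 from 1650629 to 1684882, RPS18 on chromosome 6 from 33272010 to 33276510, PSMB3 on chromosome 17 from 38752736 to 38764231 and DDR1 on chromosome 6 from 30876421 to 30900156. Of the 143 genes near absent in the rinse aid files, 53 lay in the major histocompatibility complex, 13 in 17q12 and 7 in the leukocyte receptor complex of 19q13. Transcripts outside the primary assembly were listed for 137 of them (95.8%) and for 280 of 11221 other genes (2.5%; Fisher's exact two-sided p = 4.94e-198).

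**Figure D4:**
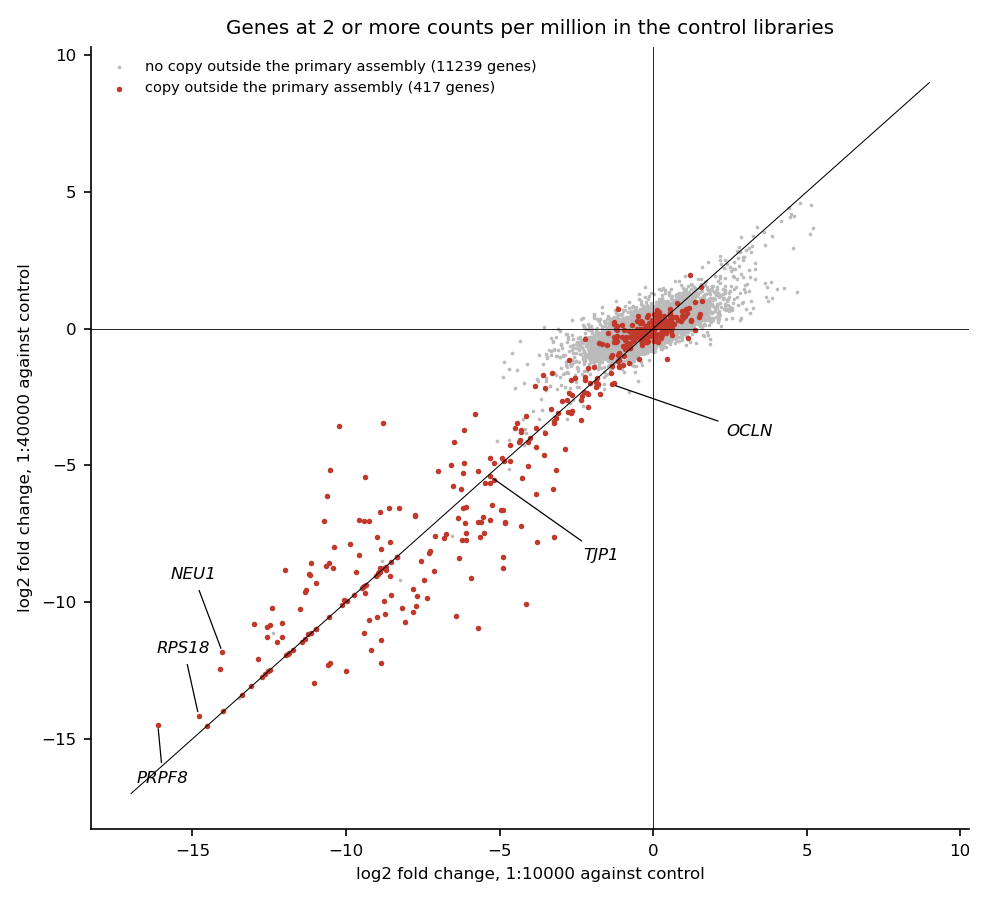
Log2 fold change at 1:10000 (horizontal axis) and at 1:40000 (vertical axis) against control for genes with at least 2 CPM in the controls, 1 point per gene. A copy outside the primary assembly was listed for 417 genes and not for 11239, which include genes that could not be searched. Genes with such copies make up most of the points far below 0 on both axes, where fitted values of genes at 0 depend on the prior count.

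Pseudogenes made up most of the highest genes against control, and 121 pseudogenes were near absent in the control files. At 1:10000 the rule named RPL14P3, YBX3P1, MRPL3P1, HSPD1P12 and MYL12BP1, which had 0, 1, 1, 2 and 2 counts over the 5 control libraries and 22.7 ± 4.86, 12.1 ± 1.77, 10.6 ± 1.67, 17.2 ± 16.9 and 12.4 ± 2.59 CPM at 1:10000. Without 1:10000 replicate 5 the mean of HSPD1P12 was 9.76 CPM. RPL14P3 (chromosome 4 from 140366240 to 140366861) was at least 320-fold higher, or 208-fold without the deepest control library. The sixth was the neurotrophin receptor NGFR, which rose from 0.194 ± 0.205 to 56.2 ± 13.6. Its log2 fold change of 8.159 was 9.127 without control replicate 2, 7.566 without control replicate 4 and 7.369 in thinned libraries. At 1:40000 they were RPL14P3, at least 267-fold higher (174-fold without that library), with SLC25A3P2, CLIC4P1, RPL7AP30, RPS7P10 and RPL8P3, at 12.9 ± 1.89, 11 ± 1.33, 22.5 ± 6.31, 18.4 ± 2.26 and 11.3 ± 1.87. Of 439 processed pseudogenes tested, 398 were higher and 14 lower at 1:10000 and 382 higher and 17 lower at 1:40000, with medians of 4.53 and 4.33, while between the dilutions 93 were higher and 11 lower with a median of 0.25. The rises of pseudogenes against control thus follow the sets of files. Aligner and annotation cannot be told apart from exposure for them.

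When the rule for the highest and lowest genes was applied to the clean subset, a step chosen after seeing the data, other genes stood at the ends, given here as log2 fold changes. At 1:10000 the highest were MT2A, a metal-binding metallothionein, at 7.34 ± 0.53 (6.73 in thinned libraries), the histone variant H3-5 at 6.09 ± 0.29, NIBAN1, a stress-response protein, at 5.69 ± 0.26, PTGS2, the inducible cyclooxygenase, at 4.69 ± 0.15, the calcium-binding protein S100P at 4.54 ± 0.20, and KLHDC7B with 2 counts in the controls and 338 at 1:10000. The lowest were the splicing factor PUF60 at -4.71 ± 0.57, KLB, a co-receptor for fibroblast growth factors, at -4.61 ± 0.26, TENT5C at -3.77 ± 0.17, TACO1, an activator of mitochondrial translation, at -3.71 ± 0.21, the claudin CLDN19 at -3.46 ± 0.22 and the hedgehog ligand IHH at -3.45 ± 0.15. At 1:40000 the highest were INHBE, an activin subunit, at 4.01 ± 0.22, S100P at 2.96 ± 0.21, HNRNPA1L3 at 2.89 ± 0.11, the kinesin KIF1A at 2.80 ± 0.18, ULBP1, a ligand of a natural killer cell receptor, at 2.67 ± 0.17, and AKNA at 2.51 ± 0.17. PUF60, TACO1, SI, SMLR1 and FGB were among the lowest, at -4.06 ± 0.49, -3.32 ± 0.19, -2.36 ± 0.38, -2.12 ± 0.19 and -2.0 ± 0.28, where SI is the brush border enzyme sucrase-isomaltase and FGB is a fibrinogen chain. PUF60 at 1:40000 ran from -3.47 without replicate 1 to -4.77 without replicate 4 of that group, and was -5.12 by limma-voom. H3-5 and HNRNPA1L3 are themselves copies of other genes, so the subset still holds genes that can share reads. PUF60 and TACO1 were nearly as low at 1:40000 as at 1:10000, a pattern they share with the near absent genes. For them too, aligner and annotation cannot be told apart from exposure.

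Between the dilutions, which share aligner and annotation, the stronger solution gave more MT2A, MT1X and PTGS2 and less of several genes whose level at 1:40000 lay closer to control. MT2A stood at 69.3 ± 26.9 CPM at 1:10000 and 1.12 ± 0.585 at 1:40000 (log2 fold change 6.13 ± 0.43), and MT1X, another metallothionein, at 12.9 ± 3.38 and 0.244 ± 0.241 (5.43 ± 0.33). Without 1:40000 replicate 1 the difference of MT2A was 5.52. PTGS2 and NGFR were higher at 1:10000, by log2 fold changes of 3.35 ± 0.14 and 3.22 ± 0.24. The lowest were NYNRIN, which stood at 24.1 ± 5.15 in the controls, 2.77 ± 0.408 at 1:10000 and 23.4 ± 3.15 at 1:40000 (-3.08 ± 0.17), the sialyltransferase ST3GAL1 at -2.86 ± 0.14, METTL7A at -2.80 ± 0.41 and NHS at -2.75 ± 0.23 (-3.49 in thinned libraries). MT2A (ENSG00000125148) lies on chromosome 16 from 56608199 to 56609497, PTGS2 (ENSG00000073756) on chromosome 1 from 186671791 to 186680427, NYNRIN (ENSG00000205978) on chromosome 14 from 24398786 to 24419288 and ST3GAL1 (ENSG00000008513) on chromosome 8 from 133454848 to 133571940. The comparison asks which responses depend on the strength of the solution. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7542 of 13157 genes passed, 3721 higher at 1:10000 and 3821 lower, of which 445 and 743 differed at least 2-fold. Under upper-quartile scaling 3323 were higher and 4289 lower. Groups did not overlap for 5302 genes (40.3%, against 0.79% by chance).

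Stress and inflammatory lists were higher at the stronger dilution, though no list passed with an estimated correlation. Immediate early genes had 19 of 22 higher and 0 lower (median 1.11, camera with Benjamini-Hochberg adjustment, adjusted p = 3.58e-12; adjusted p = 0.076 with an estimated correlation). ATF3 stood at 2.59 ± 0.10. YAP targets had 10 of 14 higher and 1 lower (median 0.66, camera adjusted p = 2.52e-07; adjusted p = 0.0639 with an estimated correlation). ANKRD1 stood at 2.78 ± 0.13. EGFR ligands and repair had 14 of 17 higher and 1 lower (median 0.85, camera adjusted p = 1.27e-05; adjusted p = 0.121 with an estimated correlation). NF-kB targets had 10 of 13 higher and 2 lower (median 0.65, camera adjusted p = 5.44e-05; adjusted p = 0.076 with an estimated correlation). ICAM1 stood at 1.35 ± 0.09. Cytokines and chemokines had 9 of 10 higher and 0 lower (median 0.77, camera adjusted p = 0.000417; adjusted p = 0.076 with an estimated correlation). CCL20 stood at 3.07 ± 0.22 (2.36 in thinned libraries). The integrated stress response had 10 of 20 higher and 3 lower (median 0.35, camera adjusted p = 5.9e-05; adjusted p = 0.076 with an estimated correlation). TRIB3 stood at 0.87 ± 0.08 and SLC7A11, which did not pass, at -0.17 ± 0.09. The unfolded protein response had 10 of 18 higher and 4 lower (median 0.30, camera adjusted p = 0.00607; adjusted p = 0.076 with an estimated correlation). Mitochondrially encoded transcripts had 12 of 13 higher and 0 lower (median 1.10, camera adjusted p = 0.000238; adjusted p = 0.244 with an estimated correlation). MT-CO1 stood at 1.10 ± 0.17, in libraries that also differed in mitochondrial ribosomal RNA.

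Further rises between the dilutions included that of ribosomal proteins, with 23 of 30 higher and 1 lower (median 0.25, camera with Benjamini-Hochberg adjustment, adjusted p = 0.00388, or adjusted p = 0.552 with an estimated correlation). Heat shock had 8 of 12 higher and 2 lower (median 0.37, camera adjusted p = 0.00723; adjusted p = 0.386 with an estimated correlation). Metallothioneins and zinc transport had 4 of 6 higher and 1 lower (median 3.71, camera adjusted p = 0.00423; adjusted p = 0.172 with an estimated correlation). That call ended with the replicate block (camera adjusted p = 0.0908). NRF2 targets had 10 of 18 higher and 3 lower (median 0.23, camera adjusted p = 0.0234; adjusted p = 0.386 with an estimated correlation). Apoptosis regulators had 11 of 23 higher and 5 lower (median 0.13, camera adjusted p = 0.046; adjusted p = 0.172 with an estimated correlation). The block ended these calls too (camera adjusted p = 0.0571 and 0.0711). The NRF2 call also ended without 1:40000 replicate 1 (camera adjusted p = 0.0582), and the apoptosis call without control replicate 2, 1:40000 replicate 1 or 1:40000 replicate 5 (camera adjusted p = 0.0557, 0.0526 and 0.0631). Heat shock and NRF2 calls ended when 1:40000 was used without its deepest and shallowest library (camera adjusted p = 0.0515 and 0.102).

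Lipid, enterocyte and proliferation lists were lower at the stronger dilution, but in the clean subset only 2 of these 10, cholesterol and fatty acid synthesis, were still called, against 7 of the 13 higher ones, where the unfolded protein response, NRF2 targets and metallothioneins lost theirs (camera adjusted p = 0.358, 0.77 and 0.124) and ribosomal proteins, heat shock and apoptosis regulators had too few members to be tested. There the calls ended for brush border (camera adjusted p = 0.0826), fatty acid oxidation (0.102), ion and water transport (0.193), stem cell and Wnt targets (0.193), DNA replication (0.102), mitosis (0.358) and hepatocyte markers (0.358), and lipoprotein assembly had too few members to be tested. Cholesterol synthesis had 2 of 23 higher and 15 lower (median -0.39, camera with Benjamini-Hochberg adjustment, adjusted p = 5.44e-05; adjusted p = 0.172 with an estimated correlation). Fatty acid synthesis had 1 of 13 higher and 9 lower (median -0.57, camera adjusted p = 5.44e-05; adjusted p = 0.076 with an estimated correlation). FASN stood at -0.93 ± 0.06. Lipoprotein assembly had 0 of 12 higher and 8 lower (median -1.0, camera adjusted p = 7.46e-05; adjusted p = 0.192 with an estimated correlation). APOB stood at -1.90 ± 0.12. Fatty acid oxidation had 1 of 14 higher and 10 lower, or 1 and 11 adjusted over the list alone (median -0.52, camera adjusted p = 0.000386; adjusted p = 0.214 with an estimated correlation). FABP1 stood at -2.30 ± 0.13. Stem cell and Wnt targets had 0 of 14 higher and 11 lower (median -0.65, camera adjusted p = 0.000417; adjusted p = 0.076 with an estimated correlation). The brush border list had 3 of 19 higher and 10 lower (median -0.58, camera adjusted p = 0.00226; adjusted p = 0.29 with an estimated correlation). HNF4A stood at -1.02 ± 0.07 and CDX2 at -1.61 ± 0.08. Ion and water transport had 1 of 14 higher and 6 lower (median -0.29, camera adjusted p = 0.00723; adjusted p = 0.0914 with an estimated correlation). AQP3 stood at -1.63 ± 0.10.

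DNA replication had 3 of 22 members higher and 12 lower between the dilutions (median -0.28, camera with Benjamini-Hochberg adjustment, adjusted p = 0.00607; adjusted p = 0.467 with an estimated correlation). Mitosis had 3 of 19 higher and 9 lower (median -0.09, camera adjusted p = 0.0234; adjusted p = 0.499 with an estimated correlation), and MKI67 stood at -1.41 ± 0.07. Hepatocyte markers had 0 of 10 higher and 5 lower (median -0.47, camera adjusted p = 0.0459; adjusted p = 0.552 with an estimated correlation). The mitosis call ended with the replicate block and without the deepest and shallowest 1:40000 library (camera adjusted p = 0.117 and 0.101). The hepatocyte call ended without 1:10000 replicate 3 or 5 and without 1:40000 replicate 1 or 2 (camera adjusted p = 0.0836, 0.0656, 0.07 and 0.0744). Tight junction genes had 7 of 22 higher and 3 lower (median 0.06, camera adjusted p = 0.34), with PATJ at 1.23 ± 0.09 and OCLN at 0.68 ± 0.14. Counts adjusted over the list alone were the same as over all genes for the lists called between the dilutions, except fatty acid oxidation. Of these 23 lists, 13 higher and 10 lower, 9 were also called in the clean subset and 0 with an estimated correlation. The interferon response and lysosome lists, not called, differed in sign between median, mean and test.

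The changes against control shared direction between the dilutions for most genes called in both. ATF3, TRIB3, SLC7A11, IL32 and PARD3 rose at both strengths, and APOB, AQP3, HNF4A and MKI67 fell at both. Genes called in both comparisons numbered 2631 higher in both and 2657 lower in both, against 1198 and 1237 for independent lists, and 150 rose at 1:10000 but fell at 1:40000 and 201 did the reverse, against 2435 with opposite directions for independent lists. FASN, the fatty acid synthase, was among these 201, at -0.69 ± 0.06 and 0.24 ± 0.06. Across the 13157 genes, which are not independent replicates, log2 fold changes had a Pearson's r of 0.918 and a covariance of 2.33, where unchanged groups simulated against the same controls gave 0.542 and 0.0426. With the controls split between the comparisons r ran from 0.871 to 0.9. In the clean subset r was 0.743 and the covariance 0.413 (simulated 0.533 and 0.0166). Any effect of aligner and annotation enters both comparisons and is part of these values. Of the genes called at 1:10000 against control, 3001 of the higher and 3016 of the lower also passed in the same direction between the dilutions, against 1296 and 1382 for independent lists. Both comparisons use the same 1:10000 libraries, which the values for independent lists leave out. Simulated unchanged groups gave 0 genes called alike in either pair of comparisons, but they leave out any effect, so this 0 says little about the overlap.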

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

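The tests of the aligner as the cause of the mitochondrial and stress response patterns, the test of shared reads in the stress response list and the other splits of the libraries were chosen only after the result was seen.

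Genes near absent in the rinse aid files, 143 in all, included PRPF8, RPS18, PSMB3, TJP1 and much of the major histocompatibility complex, where 53 of them lay between 28903002 and 33418317 on chromosome 6. Transcripts outside the primary assembly, such as those of alternate loci and patches, were listed for 95.8% of them against 2.5% of other genes, and for 93.33% against 2.42% with that complex left out. A lowering by the rinse aid would not follow the contents of the reference, and Fisher's exact two-sided p for the difference in shares was 4.94e-198, which argues against it as the main cause. Reads that fit several copies of a gene in the reference may have been discarded in the rinse aid files, which is consistent with the share but was not seen in reads. The other 6 near absent genes, and the 65 other genes with such copies that were at least 4-fold lower in both dilutions, leave open how far the pattern reaches.

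Mitochondrial ribosomal RNA rose with the rinse aid, with MT-RNR1 (chromosome M from 648 to 1601) at 464 ± 126.2 CPM in the controls, 4147 ± 415 at 1:10000 and 1726 ± 352 at 1:40000, and MT-RNR2 (1671 to 3229) at 2220 ± 461, 31880 ± 3892 and 7191 ± 2494. Aligner and annotation as the whole cause are argued against by the difference between the dilutions. On the log2 scale it was 1.27 ± 0.19 for MT-RNR1 and 2.15 ± 0.23 for MT-RNR2 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.12e-05 and 3.13e-06). Less complete selection of polyadenylated RNA was tested on other RNAs without a poly(A) tail, which it should raise too. The 6 such RNAs had a median log2 difference of 0.398 (quartiles 0.338 and 0.473), under the bound of 0.854 that a rule set beforehand derived from the ribosomal RNAs. All 6 were higher at 1:10000, from 0.064 upward, and apart from RN7SL1 their group means were at most 4.608 CPM. The test therefore cannot exclude less complete selection. Of these 6 only RNU6-574P passed, at 3.681 (edgeR adjusted p = 3.4e-09), which goes with that explanation in direction only. Its group means were 0.2632 CPM in the controls, 3.04 at 1:10000 and 0.2181 at 1:40000. At 1:40000 it thus lay no higher than in the controls, unlike the ribosomal RNAs. Its difference between the dilutions was also larger than theirs, while the others differed by 0.064 to 0.496. A single RNA with so few counts does not decide the question. The summed CPM of other RNAs without a poly(A) tail were 71.8 ± 14.3 at 1:10000 and 61.6 ± 17.3 at 1:40000 (SD, n = 5, exact two-sided permutation p = 0.325). A rise of mitochondrial transcription or RNA stability with exposure may also account for the rise of mitochondrial ribosomal RNA but was not tested. The part of the rise against control that comes from the aligner stays open.

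The integrated stress response list was higher at both dilutions, from TRIB3 at 2.86 ± 0.09 and 1.99 ± 0.09 to SLC7A11 at 2.21 ± 0.10 and 2.38 ± 0.10. At 1:10000, aligner and annotation as the whole cause are argued against by the 10 members called higher than at 1:40000, where files share both, but 3 were called lower, 7 were not called, and the list did not pass there with an estimated correlation (adjusted p = 0.076). At 1:40000, reads shared with pseudogenes or overlapping genes, or a changed gene model, are argued against by the members without any of these, all 9 of which were called higher with a median of 1.461 on the log2 scale. Aligner and annotation cannot be told apart from exposure for the rise at 1:40000, since the number of control libraries with the rinse aid files' aligner header was 0. A response to the rinse aid may be the cause at both strengths, as a hypothesis found and tested on the same data.

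For the number of genes called, 100 splits of the 10 libraries were drawn for each comparison, and only the real 1 of the 100 reached its own count. At 1:10000 against control the real split called 9343 genes and the highest other split 0, at 1:40000 against control 6858 and 1, and between the dilutions 7542 and 1987. The split with 1987 genes exchanged 1 library of each group. A share of 1 in 100 is the smallest that these splits can give. They argue against a chance assignment of libraries, but do not separate exposure from the aligner.

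The effects of the dilutions differed for the 7542 genes that passed between them. In the comparisons with control, 150 genes were higher at 1:10000 and lower at 1:40000 and 201 were lower at 1:10000 and higher at 1:40000. Any effect of aligner and annotation is part of these directions. In data no comparison used, 10 of 10 rinse aid libraries had counts on second copies of pseudoautosomal genes, from 12 to 3792 counts, where the control libraries had 0.

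Single libraries stood apart from their group by Dixon's test in 17 of 186 groups of values tested, where chance gives 9.3. In the controls, AQP3 was 166.031 CPM in replicate 2 and ATF3 8.269 in replicate 5. TAF15 was 105.645 in replicate 1, and MT-CO3 was 1836.206 in replicate 3, each the lowest. Pseudogenes took 0.248% of counts in control replicate 2, the highest. At 1:10000, OCLN was 22.7 in replicate 1 against 12.989 to 13.503 in the others, HSPD1P12 was 47.181 in replicate 5, and FASN was 343.9 in replicate 2, the lowest. The same replicate 2 had the highest share of mitochondrial ribosomal RNA, 3.833%, and its top 10 genes took 9.89% of counts. At 1:40000, replicate 1 held 172.09 M counts against 2.55 M to 25.96 M in the others, with ATP1B1 lowest at 287.716, EGFR highest at 118.413 and PATJ highest at 28.434. In replicate 2 of 1:40000, HSPD1P12 was 24.825 and RPL7AP30 33.609, the highest, and TGM2 117.633, the lowest. By library, 1:40000 replicate 1 had 4 such values and 1:10000 replicate 2 and 1:40000 replicate 2 had 3 each.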

How the results depend on the processing

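The clean subset, the genes left out for near absence or copies outside the primary assembly, the limit to calls with the same direction between the dilutions, the thinned libraries, the sizes without mitochondrially encoded genes and 1:40000 without its deepest and shallowest library were tests chosen only after the result was seen.

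Counts of genes called stayed within 1.5 times of the reported ones under other scalings, filters and tests, the fit of the compared groups alone, thinning and the replicate block, from 7456 (thinned) to 10392 (no filter) at 1:10000 against control, from 4947 (thinned) to 7468 (limma-voom) at 1:40000 against control and from 5828 (thinned) to 8012 (replicate block) between the dilutions. A threshold of 2-fold left 3070, 1361 and 1188 genes, since fewer qualify. The clean subset, refitted alone, called 3237, 2332 and 2817, since fewer genes were tested. Calls with the same direction between the dilutions numbered 6017 at 1:10000 and 2597 at 1:40000. Without the low-count filter, 4494 genes were higher and 2931 lower at 1:40000 against control, in place of 3439 and 3419, and upper-quartile scaling gave 4031 and 2900. Between the dilutions, where 3721 were higher and 3821 lower, these alternatives gave 3210 and 4366, and 3323 and 4289. With single libraries left out, counts ran from 9053 to 9555, from 6254 to 6971 and from 7075 to 7624.

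Lists called at 1:10000 against control, 19, became 1 with an estimated correlation, 30 with fry and 7 in the clean subset. At 1:40000 against control, 2 became 1 with an estimated correlation, 23 with fry, 4 thinned, 4 in the clean subset and 11 without near absent genes. Of the 2, only the integrated stress response was among these 11, and the lists gained are not named here. Between the dilutions, 23 became 0 with an estimated correlation, 32 with fry and 9 in the clean subset. Fry asks whether members move on balance in 1 direction, not whether they differ from other genes. With single libraries left out, lists called ran from 18 to 20, from 2 to 3 and from 20 to 23. The fatty acid synthesis list at 1:10000 against control turned direction in the clean subset (camera adjusted p = 0.947) with fewer members tested. Thinning ended the calls of cholesterol synthesis and lysosome at 1:10000 (camera adjusted p = 0.0513 and 0.108) and of apoptosis regulators and metallothioneins between the dilutions (0.0551 and 0.113). For other losses the cause was not tested.

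The correlation of the dilutions' changes, 0.918, was 0.887 as a mean over split controls, 0.743 in the clean subset, and from 0.909 to 0.92 with single libraries left out, lowest without 1:40000 replicate 1 (0.909) and replicate 3 (0.912); the cause was not tested. The genes named by the rule, in all genes or in the clean subset, kept their direction and their side of the threshold, where a value was given, under other scalings, filters and tests, the fit of the compared groups alone, the replicate block, thinning, sizes without mitochondrially encoded genes and the leaving out of libraries. This does not extend to genes named in other ways. Among the fatty acid synthesis genes named below, 5 in place of 6 had calls in opposite directions with DESeq2 size factors. With a 2-fold threshold, named genes such as FASN and RBP4 at 1:10000 and IL32 and CXCL16 at 1:40000 would not qualify. Counting single genes and single lists together, 3838 values under alternatives kept both, 95 list calls kept their direction but not the call, and 1 list turned.

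Replicate numbers are shared by the groups, but no label says that a number marks a shared day or passage. Deviations of libraries with the same number correlated from -0.05 to 0.058 between control and 1:10000, from 0.06 to 0.135 between control and 1:40000 and from 0.045 to 0.281 between the dilutions, and the own number was the best partner for 1, 3 and 3 of 5 libraries. Not every correlation was over 0.1, so the numbers were not taken to pair the samples. That rule looks at single numbers and cannot tell whether replicates 1 and 2 differ together from 3 to 5. As a hint from the data, the third principal component (2.9% of the variance) set replicates 1 and 2 above the other 3 in every group. Pearson's chi-squared of counts per degree of freedom, 1 under sampling alone, was 1.729 to 2.152 between control replicates 3 to 5. Pairs with control replicate 1 or 2 gave 4.278 to 8.341. The ranges were 1.918 to 2.511 and 4.571 to 8.465 at 1:10000, and 2.612 to 4.832 and 3.463 to 48.851 at 1:40000, where depths differed most. The numbers thus carry shared structure, which the main fit leaves out. With the replicate block 9592, 7314 and 8012 genes were called, and lists called became 19, 5 and 19, with lysosome lost (camera adjusted p = 0.0556) and metallothioneins gained at 1:10000. The block changed the calls of lists named with it, and of no gene named by the rule in all genes or in the clean subset. The shallowest library, at 1:40000, held 2551839 counts, but over the group 3 counts equalled 0.0135 CPM there against 0.0872 at 1:10000 and 0.0711 in the controls.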

Other observations

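The test of lipid synthesis genes under other scalings and every gene named in this part were chosen only after the result was seen.

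Some lipid synthesis genes went in opposite directions from control at the dilutions. Aligner and annotation cannot be told apart from exposure in these directions, and only the difference between the dilutions shares both. Of the fatty acid synthesis list 6 genes, FASN, ACLY, ACSS2, FADS1, ELOVL6 and TMEM97, fell at 1:10000 and rose at 1:40000, and of cholesterol synthesis FDPS, MVD and DHCR7 were among those that did. FASN, the fatty acid synthase, stood at 577 ± 32.9 CPM in the controls, 358 ± 7.96 at 1:10000 and 683 ± 50.6 at 1:40000. With DESeq2 size factors 5 genes of the fatty acid synthesis list were called in both these directions and with upper-quartile scaling 6. The amino acid transporter SLC38A3 moved likewise, at 42.4 ± 9.19, 18.5 ± 4.11 and 86.5 ± 21.2. In the other direction, the chaperones HSPH1 and HSPA4 and the endoplasmic reticulum chaperone HSPA5 rose at 1:10000 and fell at 1:40000, HSPH1 by 0.45 ± 0.12 and -0.48 ± 0.12.

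CYP1A1, CYP1B1, TIPARP, SLC2A1 and HK2 were higher at 1:10000 although the fixed lists nearest to them, xenobiotic metabolism and glycolysis, did not pass at 1:10000 against control (camera adjusted p = 0.291 and 0.748). CYP1A1, which oxidises polycyclic aromatic compounds, rose from 9.03 ± 1.18 in the controls to 117 ± 36.4 at 1:40000 and 337 ± 42.8 at 1:10000, with CYP1B1 at 0.984 ± 0.170, 2.04 ± 0.242 and 6.91 ± 1.38 and TIPARP, a repressor of the aryl hydrocarbon receptor, at 23.9 ± 3.57, 30.8 ± 3.15 and 80.5 ± 10.7. The glucose transporter SLC2A1 stood at 342 ± 19.6 in the controls, 450.4 ± 61.1 at 1:40000 and 1332 ± 178 at 1:10000, and the hexokinase HK2 at 43.1 ± 6.65, 52.0 ± 5.74 and 165 ± 21.4. The growth factors AREG and EREG, ligands of EGFR, rose from 108 ± 5.40 to 544 ± 133 and from 36.8 ± 7.69 to 323 ± 108 at 1:10000. IHH, the hedgehog ligand of differentiated enterocytes, stood at 51.6 ± 6.0, 25.3 ± 4.44 and 4.69 ± 1.16 in the same order as CYP1A1, and LGR5, a receptor of intestinal stem cells, at 20.1 ± 3.18, 6.13 ± 2.28 and 2.18 ± 0.983.

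Several list members had too few counts to be tested. Summed over the 5 libraries of a group, the neutrophil chemokine CXCL8 had 0 counts in the controls, 47 at 1:10000 and 13 at 1:40000, and CXCL1 had 1, 38 and 17. The metallothionein MT1G had 0, 24 and 0 counts, MT1H 0, 16 and 0, and the stress hormone FGF21 0, 16 and 85. These sums come from groups that differ in depth. HSPA1A, a heat shock gene in the major histocompatibility complex, had 21, 1 and 0.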
